A study of Mus musculus with 3 samples.

How the data were processed

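The samples were 3 single-cell RNA sequencing libraries of dorsal skin from C57BL/6 mice, 1 library for each of 3 ages: neonatal, 3 weeks and 2 months. According to the sample descriptions, minced biopsies were digested with collagenase D and DNase, and libraries came from a droplet kit that captures the 3' ends of transcripts and were sequenced on a NovaSeq instrument. The deposited files hold raw UMI counts per gene and barcode, as whole numbers with no normalization by the authors, and each matrix lists 27998 genes by Ensembl identifier and symbol. The submitters' notes name Cell Ranger 3.0.2, Seurat 2.0 and the mm10 build, and do not state how barcodes were chosen. How many animals went into a library is not stated.

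Each library was filtered to barcodes with 300 or more detected genes, 500 or more UMIs and at most 10% mitochondrial UMIs, which left 7911, 8900 and 9332 barcodes in the neonatal, 3 week and 2 month libraries. Doublets were called with the Scrublet method of scanpy 1.11.5 at an expected rate of 0.06. Its own threshold marked 0.0253% of the neonatal barcodes, under the 0.5% set as the lowest acceptable share, so the 6% with the highest score were removed there (475 barcodes). In the 3 week and 2 month libraries 238 and 362 were removed by that threshold. Median mitochondrial shares of kept cells were 3.62%, 3.04% and 2.60%. Counts were normalised per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (leidenalg 0.10.2) were used on the 3 libraries together, with no integration and without the genes of the fixed lists. Clusters were named by markers fixed for 19 cell types. The type with the best marker score gave the name, unless 3 or more of the leading 10 genes marked another class. That class then gave the name if it had more such genes. In this way cluster 33 was named dendritic or Langerhans-like, although 6 of 6 T or innate lymphoid markers were detected. Likewise cluster 34 was named mural-like, although 7 of 7 fibroblast markers were detected. A cluster was left unnamed where its leading 10 genes held more than 1 marker of each of more than 1 class. It also stayed unnamed where they held no marker of its class. Fibroblast-like and keratinocyte-like clusters were exempt from this last rule unless their UMI counts were low. A cluster led by adipocyte genes, or with high UMI counts and markers of another class, was left unnamed too. Fibroblast-like cells were clustered again within each library, and subclusters were named by markers of 7 states. The 12 preadipocyte markers and the rest of the adipocyte list could enter the variable genes there, and the other lists were left out. The state with the highest mean marker ratio was taken among those with at least 3 markers detected. A subcluster stayed unnamed where its leading 10 genes held more markers of another state, or 3 or more of another class.

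Ages were compared in the fibroblast-like class by counts summed over the cells of each library, 58124174, 68759271 and 53589993 UMIs, as CPM over all genes with exact Poisson intervals. With 1 library per age there is no replicate error, so no p-value is given for any difference between ages, and cells were not used as replicates. For each of 20 gene lists the members measured at 10 CPM or more in at least 1 library were counted by whether CPM differed at least 2-fold, and the median log2 ratio was placed among 10000 random lists of the same size matched on mean expression. Percentiles below 2.5 or above 97.5 are called apart from random lists. The lists hold the adipocyte programme, adipose progenitor, IL-1 family and receptors, NF-kB response, WNT target, WNT ligand and receptor, WNT antagonist, collagen and matrix, matrix turnover, cell cycle, TGF-beta and BMP, imprinted and growth, interferon and antigen presentation, antimicrobial and acute phase, fibroblast chemokine and complement, hair follicle mesenchyme, dissociation and heat shock, sex-linked, resident macrophage and inflammatory myeloid genes. Together they name 381 genes found in the files. Some genes are in more than 1 list, such as C3, Dlk1, Cxcl2, Igf1 and Icam1. A count under 3 was set to a floor of 3 counts and the ratio given as a bound.

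Shares of cells with a UMI were computed after thinning each cell to 1500 UMIs with a fixed seed, leaving out shallower cells (54, 12 and 108 fibroblast-like cells), with exact Clopper-Pearson intervals and with keratinocyte-like cells as the class that should lack adipogenic genes. Cebpa was not given alone there, since keratinocytes express it, but it was counted among the 12 preadipocyte markers in both classes. All intervals and floors cover counting error only.

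Preadipocyte-like and other fibroblast-like cells were compared in libraries with 50 or more cells of each, which left the neonatal and 3 week libraries and 4 summed profiles. The test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 with TMM scaling, filterByExpr and library as a block. Benjamini-Hochberg adjustment at 0.05 was made over all genes and over each list alone. Standard errors (±) were the absolute log2 ratio over the square root of the F statistic. They rest on dispersion shared across genes and are not a spread measured between libraries. Lists were tested with camera of limma 3.58.1 at its preset correlation, and again with the correlation estimated from 1 residual degree of freedom. With so few degrees of freedom the second form had little power to pass any list. The fit was tested on simulated data with the same library sizes, where it called 96 of 97 genes changed 4-fold, 43 of 103 changed 2-fold and 5 unchanged genes. The changed genes were drawn from the more abundant genes, and all genes had 1 common dispersion. These rates therefore need not hold for less abundant genes or where dispersion varies between genes. In counts drawn from Poisson distributions for the comparison of ages the Poisson intervals covered 94.7% of the true ratios. That coverage follows from how the counts were drawn and does not bear on variation between cells or libraries. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and DESeq2 1.42.0 were also used.

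Genes to be named were set by rule. In each pair of ages these were up to 4 members per list with the largest ratio among those at 20 CPM or more, and outside the lists the 10 highest and 10 lowest ratios among genes at 100 CPM or more and detected in 10% of cells, leaving out mitochondrial, ribosomal-protein, haemoglobin, sex-linked and marker genes and genes over 5 times more abundant in another class. In the state comparison they were up to 4 members per list with the lowest adjusted p among those passing. The text gives part of each set. By class they were the IL-1 ligands and receptors and the WNT ligands, in classes of 50 or more cells. Gene positions were taken from the GENCODE annotation of mm10 by Ensembl identifier, where all 513 named or listed genes were found, 508 of them under the same symbol.

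The filters, markers, lists, comparisons, naming rule and most alternatives were chosen before the data were examined. Those alternatives were a 5% mitochondrial limit, no doublet removal, Leiden resolutions of 0.5 and 2, clustering each library on its own or with the list genes, TMM scaling, CPM without mitochondrial, ribosomal-protein and haemoglobin genes, no minimum CPM, the mean over cells of CPM per cell, thinning to 1000 UMIs or none, DESeq2 and its size factors, no filter on low counts, no library block, each library left out in turn, and an estimated correlation in camera. Subsets of fibroblast-like cells, narrower sets of other cells in the state comparison, and neonatal cells with a Y-linked UMI and no Xist UMI were added after the data were seen. Cells of unnamed clusters were left out of all comparisons.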

Results

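Dissociated dorsal skin of C57BL/6 mice was profiled by droplet single-cell RNA sequencing at 3 ages, neonatal, 3 weeks and 2 months, with 1 library per age. The series concerns IL-1 and WNT signalling in cells of the dermal adipocyte lineage. The comparisons follow the dermal fibroblast-like cells with age, ask which of them carried adipogenic markers, and ask which cell classes held the transcripts of both pathways. The deposited matrices held 84086755 unique molecular identifier (UMI) counts on 8452 barcodes for the neonatal library, 113874172 on 10226 for the 3 week library and 98432611 on 10190 for the 2 month library. After filtering, 7436, 8662 and 8970 cells were kept, with medians of 8510.5, 10987 and 8280.0 UMIs per cell. There were no replicates at any age. Intervals are 95% intervals for counting error, exact Clopper-Pearson for shares and exact Poisson for counts scaled to the UMI total of a cell class in a library (CPM). No difference between ages was tested. Cell classes carry the suffix -like because they rest on marker transcripts.

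Fibroblast-like cells, marked by Pdgfra, Dcn and Lum, were the largest class in each library and made up a smaller share of the older libraries. They were 85.6% of neonatal cells (84.7 to 86.3%, 6362 cells), 63.9% at 3 weeks (62.8 to 64.9%, 5531 cells) and 53.6% at 2 months (52.5 to 54.6%, 4806 cells). Keratinocyte-like cells, the epithelial cells of epidermis and hair follicle, made up 2.60%, 16.1% and 18.8%. T or innate lymphoid-like cells were 1 cell in the neonatal library, 0.0134%, against 1.67% at 3 weeks and 3.77% at 2 months. A further cluster led by lymphocyte genes, cluster 9, held 43, 271 and 661 cells. All 6 measured T or innate lymphoid markers were detected in it, but none was among its leading 10 genes, so it stayed unnamed. Fibroblast-like and keratinocyte-like clusters were exempt from that rule. At resolution 2 the T or innate lymphoid-like class held 38 neonatal cells, 3.14% and 8.15%. Macrophage-like cells made up 1.48%, 2.07% and 2.93%. Schwann-like cells made up 1.69%, 2.94% and 4.75%, and mast-like cells 1.26%, 0.808% and 0.156%. Melanocyte-like cells made up 0.121%, 0.358% and 1.36%, sebaceous-like cells 0.0269%, 0.531% and 1.17%. Mural-like cells made up 2.58%, 3.58% and 2.55%, and endothelial-like cells 0.524%, 1.22% and 0.502%. The smaller classes depended on filters and clustering. With a 5% mitochondrial limit mural-like shares were 1.40%, 0.709% and 0.608% and melanocyte-like shares 1.51%, 1.46% and 1.90%. Sebaceous-like shares were 1.71%, 1.62% and 2.096% at resolution 0.5. With each library clustered on its own no neonatal cells were named macrophage-like or melanocyte-like, and keratinocyte-like cells were 4.13% of neonatal cells. Dendritic or Langerhans-like cells were 0 of 7436 neonatal cells, which allows a share of up to 0.0496%, against 0.877% and 0.691% in the older libraries. Between 4.14% and 9.70% of the cells of a library stayed unnamed. The shares describe the cells that dissociation released, and the differences between libraries were not tested.

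**Figure D1:**
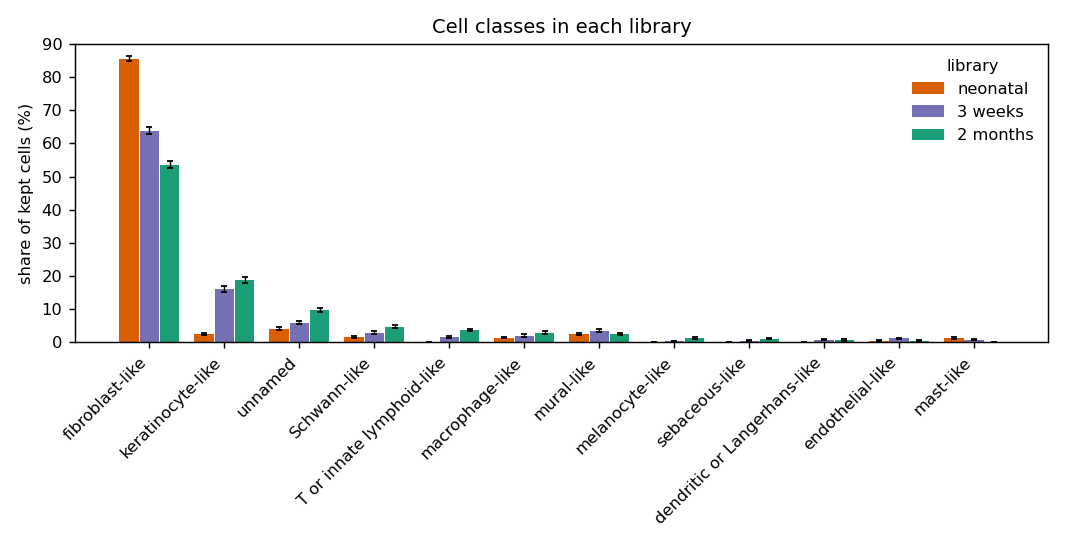
Share of kept cells (percent, vertical axis) in each cell class (horizontal axis) for the neonatal, 3 week and 2 month libraries, 1 library per age; bars are shares and whiskers exact 95% Clopper-Pearson intervals. Fibroblast-like cells stood at 85.6%, 63.9% and 53.6% and keratinocyte-like cells at 2.60%, 16.1% and 18.8%.

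The fibroblast-like class was itself divided by library, since different clusters held most of its cells at each age. Of its 17 clusters, clusters 1, 3, 6, 7 and 20 held 92.0% of the neonatal cells, clusters 0 and 14 held 51.1% of the 3 week cells, and clusters 2, 10 and 24 held 57.6% of the 2 month cells. Each of these clusters took at least 90% of its cells from that library. Preadipocyte-like cells, called within each library by Pparg, Fabp4, Cd36 and further adipogenic markers, were 291 neonatal cells (4.57% of the class, 4.07 to 5.12%) and 240 cells at 3 weeks (4.34%, 3.82 to 4.91%). These shares depended on the clustering, at 15.6% and 13.7% with resolution 0.5 and 9.37% and 3.72% when clustered with the list genes. No subcluster of the 4806 fibroblast-like cells at 2 months was named so. The same held at resolutions 0.5 and 2, with the list genes and with doublets kept, the other settings in which states were named. The smallest subcluster there held 44 cells, so a group of a few cells could not have been seen. Interstitial progenitor-like cells, marked by Dpp4 and Pi16, made up 2.48%, 6.76% and 16.9% of the class. Papillary-like cells made up 9.48%, 1.10% and 0.916%, reticular-like cells 7.70%, 14.1% and 9.28%, with 4.48% in the neonatal library when doublets were kept. Dermal papilla-like cells made up 14.2% and 6.15% in the neonatal and 3 week class, and dermal sheath-like cells 7.89% and 7.55% in the neonatal and 2 month class. Neither zero in the remaining library shows absence. The 340 dermal papilla-like cells at 3 weeks had 5 markers of each state, and at resolution 2 the class split into 35 dermal papilla-like and 304 dermal sheath-like cells (5.50%). At 2 months 71 cells with 8 dermal papilla markers stayed unnamed, because their leading genes pointed to another state. Tendon or fascia-like cells made up 6.11% at 3 weeks and 3.27% at 2 months, with 0 of 6362 neonatal cells, but 7.25% and 12.4% at resolution 0.5, so the order of the older libraries depended on the clustering. Papillary-like cells were 5.71% of the neonatal class at resolution 2, and none were named at resolution 0.5. The states of 53.6%, 61.5% and 62.0% of the class could not be named.

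Fabp4 transcripts were detected in smaller shares of the older libraries at equal depth. Each cell was thinned to 1500 UMIs. Fabp4, which encodes a fatty acid binding protein of adipocytes, was then detected in 9.02% of neonatal fibroblast-like cells (8.32 to 9.75%), 1.99% at 3 weeks (1.64 to 2.40%) and 0.234% at 2 months (0.117 to 0.419%). Keratinocyte-like cells, which should lack it, gave 1.55%, 0.287% and 0.119%, so the 2 month share lay within the interval of this background. The nuclear receptor gene Pparg was detected in 2.01%, 0.779% and 0.128% of fibroblast-like cells, against 1.55% (0.322 to 4.48%), 0 of 1394 and 0 of 1681 keratinocyte-like cells, so its neonatal share lay within the interval of the background. Cells with a UMI of 3 or more of the 12 preadipocyte markers were 3.20% (2.78 to 3.67%), 0.834% (0.611 to 1.11%) and 0.149% (0.0599 to 0.307%), against 0.518%, 0.0717% and 0 of 1681 keratinocyte-like cells (up to 0.219%, so the 2 month share was not above the background). Plin2, a lipid droplet coat gene, was detected in 7.70%, 6.12% and 6.07% of fibroblast-like and 3.63%, 3.01% and 1.73% of keratinocyte-like cells. The lipoprotein lipase gene Lpl, which did not follow this order, was detected in 12.7%, 23.2% and 21.2% against 1.04%, 0.933% and 0.476%. Dlk1, an early preadipocyte and reticular fibroblast gene, was detected in 34.7%, 4.95% and 0.553% of fibroblast-like cells against 1.04%, 0% and 0.0595%, and Pi16 in 2.14%, 19.1% and 33.95% against 0%, 0.646% and 1.31%. The decoy receptor gene Il1r2 was detected in 0.872%, 23.0% and 46.7%, with 1.55%, 16.2% and 8.33% in keratinocyte-like cells. Il1r1, the signalling receptor, was detected in 5.01%, 5.60% and 8.195% against 2.07%, 1.65% and 2.86%, and its co-receptor Il1rap in 2.16%, 6.41% and 6.39% against 1.55%, 3.16% and 1.31%. The neonatal shares of Il1r2, Il1r1 and Il1rap lay within the intervals of the 193 neonatal keratinocyte-like cells. Keratinocyte-like cells of the older libraries held Il1r2 themselves, so for these receptor genes they are a comparison and not a background. Median depths before thinning were 8495.0, 12114 and 10145.5 UMIs in fibroblast-like cells and 21865, 12121 and 10743 in keratinocyte-like cells.

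**Figure D2:**
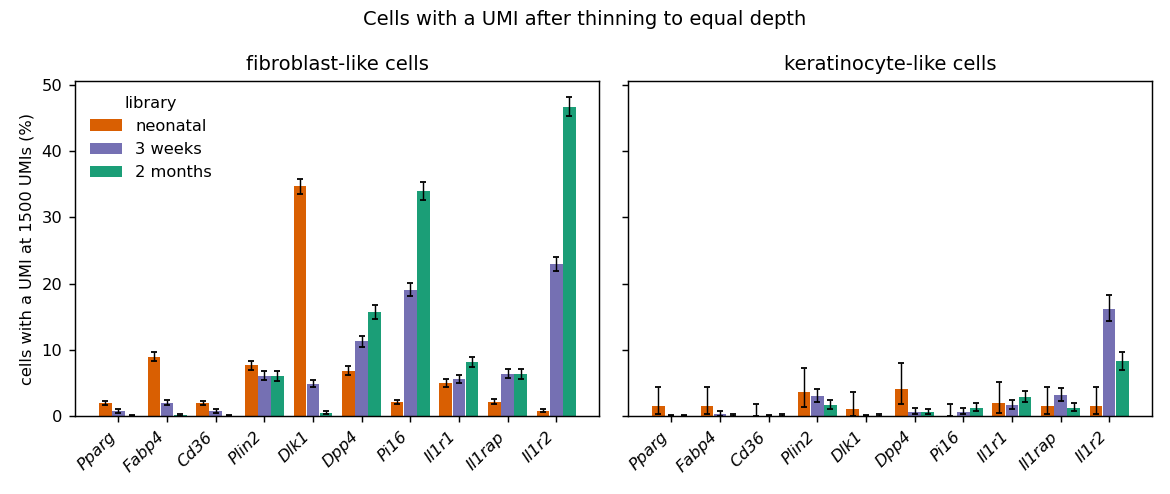
Percent of cells with at least 1 UMI of each gene after thinning every cell to 1500 UMIs (vertical axis), in fibroblast-like cells (left) and keratinocyte-like cells (right) of the 3 libraries; whiskers are exact 95% Clopper-Pearson intervals. In fibroblast-like cells Fabp4 stood at 9.02%, 1.99% and 0.234% and Il1r2 at 0.872%, 23.0% and 46.7% from the neonatal to the 2 month library.

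At 3 weeks the fibroblast-like class showed higher CPM of IL-1 list, interferon, complement and matrix turnover genes than in the neonatal library. CPM of WNT target genes was lower. Of the 299 measured members of the 20 lists fixed in advance, 80 had at least 2-fold higher and 54 at least 2-fold lower CPM. The excess of higher members depended on scaling, with 67 and 67 without mitochondrial, ribosomal-protein and haemoglobin genes and 93 and 43 with TMM scaling. Over all 8789 measured genes 808 were higher and 976 lower. In the IL-1 list 6 of 11 measured members had higher and 0 lower CPM. Their median log2 ratio was 1.30, above all of 10000 random lists matched on expression. Il1r2 stood at 199 against 6.07 CPM (log2 ratio 5.03, 4.88 to 5.19) and Il1rap at 46.0 against 16.5. The inhibitory kinase gene Irak3 stood at 23.5 against 9.31 and the adaptor gene Myd88 at 42.5 against 66.7. The signalling receptor gene Il1r1 differed little, at 41.7 against 38.9 CPM. In the WNT target list 0 of 14 members had higher and 6 lower CPM (median -0.73, percentile 0.39). Lef1, a transcription factor gene of the pathway, stood at 7.18 against 59.7 CPM (log2 ratio -3.05, -3.19 to -2.92) and Tcf7 at 13.8 against 55.2. The feedback inhibitor gene Nkd2 stood at 37.1 against 99.7 and Twist2 at 157 against 389. WNT antagonist genes went both ways, 3 higher and 4 lower of 14 (median -0.70, percentile 0.73). Dkk1 stood at 2.15 against 23.5, Wif1 at 38.2 against 276, Sfrp4 at 119 against 26.7 and Dkk2 at 61.8 against 14.985. Among WNT ligands and receptors 2 of 22 had higher and 4 lower CPM (median -0.09, percentile 77.8). The R-spondin gene Rspo3 stood at 21.5 against 172, Wnt6 at 9.45 against 29.6 and Wnt5a at 73.4 against 31.2.

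Single adipogenic and fetal growth genes such as Fabp4, Dlk1 and Igf2 had higher CPM in the neonatal library, while the adipocyte and the imprinted and growth lists lay inside the random range. Fabp4 stood at 27.9 CPM at 3 weeks against 498 in the neonatal library (log2 ratio -4.16, -4.23 to -4.09) and Cd36 at 6.27 against 25.2. Scd1, a fatty acid desaturase gene, stood at 47.1 against 11.1 and Ebf2 at 20.7 against 7.45. The adipocyte list as a whole had 3 of 20 members with higher and 6 with lower CPM (median -0.41, percentile 16.2). The adipose progenitor list had 4 of 12 higher and 2 lower (median 0.58, percentile 96.7). Dlk1 stood at 67.2 against 2003 CPM (log2 ratio -4.90, -4.94 to -4.85), Ly6c1 at 665 against 53.6 and Pi16 at 366 against 37.8. In the imprinted and growth list 4 of 19 members had higher and 8 lower CPM (median -0.19, percentile 32.1). Igf2 stood at 19.008 against 215, H19 at 125 against 889.6 and Igfbp5 at 1318 against 98.1. Cell cycle genes had 0 of 24 members higher and 7 lower (median -0.53, percentile 2.19), among them the replication helicase gene Mcm6 at 11.4 against 36.7.

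The interferon, chemokine and complement, and matrix turnover lists stood higher at 3 weeks. Interferon and antigen presentation genes had 12 of 17 members with higher and 0 with lower CPM (median 1.73, percentile 100). The class I gene H2-K1 stood at 730.4 against 69.3 CPM and the immunoproteasome gene Psmb8 at 45.4 against 4.80. Fibroblast chemokine and complement genes had 9 of 11 higher and 0 lower (median 2.64, percentile 100). C4b stood at 24.8 against 3.32 and the complement inhibitor gene Serping1 at 1086 against 149.7. The antimicrobial list had only 2 measured members, C3 at 107 against 2.68 (log2 ratio 5.32) and Cp at 46.4 against 20.3. Matrix turnover genes had 10 of 16 members higher and 1 lower (median 1.19, percentile 99.99). The protease gene Mmp3 stood at 169 against 4.82 and Ctsk at 711 against 239.6. The collagen and matrix list had 9 of 30 higher and 4 lower (median 0.15, percentile 90.01). Tnc stood at 8.62 against 89.7, Col12a1 at 46.3 against 321 and Sparc at 51238 against 9414. The NF-kB response list had 4 of 26 higher and 1 lower (median -0.03, percentile 68.4), with Cxcl2 at 225 against 621. TGF-beta and BMP genes split 4 and 4 of 23 (median -0.15, percentile 57.4). Hair follicle mesenchyme genes split 3 and 3 of 10 (median -0.28, percentile 35.1), with the hedgehog pathway genes Gli1 at 17.6 against 79.4 and Ptch1 at 28.2 against 126. The 3 measured resident macrophage genes all had higher CPM (median 1.71, percentile 96.7). Of 4 inflammatory myeloid genes 1 had higher and 2 lower CPM (median -0.80, percentile 1.85). Outside the lists Ifi205 (158 against 2.91), Clec11a (319.5 against 6.40) and Cgref1 (185 against 3.89) had the highest ratios. Col26a1 (3.26 against 189), Egfl6 (15.6 against 565) and Gm1673 (23.2 against 239) had the lowest.

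**Figure D3:**
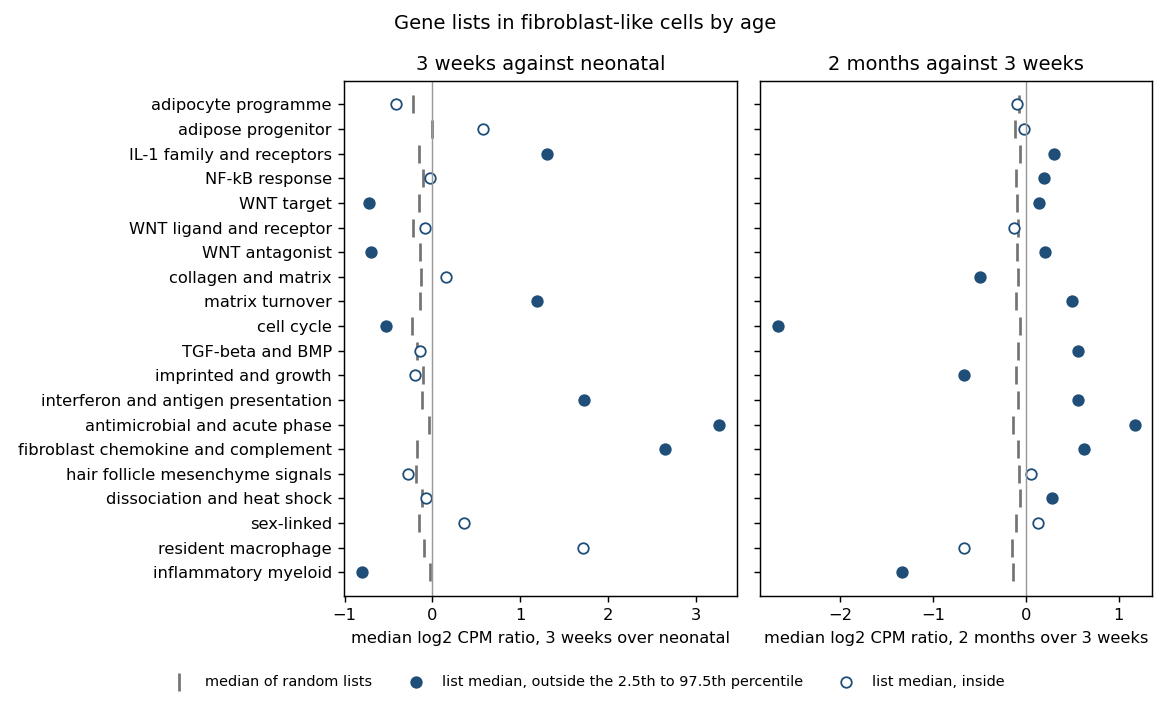
Median log2 CPM ratio of the measured members of each gene list in fibroblast-like cells (horizontal axes, with different ranges), 3 weeks over neonatal (left) and 2 months over 3 weeks (right), 1 library per age. Filled points lie outside the 2.5th to 97.5th percentile of 10000 random lists matched on expression, open points inside, and bars mark the median of the random lists. The IL-1 list stood at 1.30 and 0.30, the WNT target list at -0.73 and 0.14, and the cell cycle list at -0.53 and -2.66.

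From 3 weeks to 2 months the largest shift of any list in the fibroblast-like class was in cell cycle genes. Of these, 0 of 24 had at least 2-fold higher and 22 at least 2-fold lower CPM (median log2 ratio -2.66, percentile 0). Top2a, the topoisomerase of dividing cells, stood at 3.43 against 32.7 CPM, Birc5 at 2.67 against 32.4 and Cdk1 at 2.46 against 25.5. Imprinted and growth genes had 0 of 19 higher and 7 lower (median -0.67, percentile 0), with H19 at 0.448 against 125 and Dlk1 at 2.61 against 67.2. Collagen and matrix genes had 0 of 30 higher and 8 lower (median -0.49, percentile 0), with Fbn2 at 10.5 against 64.2 and Postn at 283 against 1015. Over all 299 measured list members 27 had higher and 51 lower CPM, and over all 8791 measured genes 287 and 352. The balance of list members was 37 and 38 with the mean of CPM per cell, and turned to 51 and 34 in interstitial progenitor-like and 51 and 39 in reticular-like cells alone. The IL-1 list had 2 of 11 higher and 0 lower (median 0.30, percentile 99.6). Il1r2 stood at 578 against 199 CPM (log2 ratio 1.54, 1.51 to 1.57) and the alarmin gene Il33 at 22.7 against 5.93. The NF-kB response list had 3 of 26 higher and 1 lower (median 0.20, percentile 99.9). C3 stood at 737 against 107, Tnfaip2 at 108 against 37.3, the cyclooxygenase gene Ptgs2 at 418 against 178 and Cxcl2 at 89.8 against 225. In the WNT target list 2 of 14 had higher and 0 lower CPM (median 0.14, percentile 97.8, which was 97.0 with TMM scaling), with Lef1 at 23.3 against 7.18 and Bambi at 64.1 against 29.2. WNT antagonists had 2 of 14 higher and 1 lower (median 0.21, percentile 98.5), led by Dkk2 at 199 against 61.8. WNT ligands and receptors had 0 of 22 higher and 2 lower (median -0.13, percentile 30.6), with Fzd4 at 12.8 against 27.6.

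Matrix turnover genes (3 higher and 1 lower of 16, median 0.50), TGF-beta and BMP genes (2 and 0 of 23, median 0.57), interferon genes (4 and 0 of 17, median 0.56) and chemokine and complement genes (3 and 0 of 11, median 0.62) all lay above every random list at 2 months. Among them Mmp3 stood at 555 against 169 CPM, Ctsk at 2570.1 against 711, Id3 at 1657 against 688 and B2m at 894 against 375. The B cell chemokine gene Cxcl13 stood at 109 against 11.0. Fabp4 stood at 2.20 against 27.9 (log2 ratio -3.66, -3.94 to -3.39), while the adipocyte list had 2 of 20 higher and 5 lower members (median -0.10, percentile 40.0). The adipose progenitor list had 1 of 12 higher and 2 lower (median -0.02, percentile 73.5), with Pi16 at 1142 against 366. The antimicrobial list had 1 of 2 higher (median 1.17, percentile 98.4). Hair follicle mesenchyme genes had 1 higher and 2 lower of 10 (median 0.05, percentile 84.3), and resident macrophage genes 1 higher and 0 lower of 3 (median -0.66, percentile 6.49). Inflammatory myeloid genes had 1 higher and 3 lower of 4 (median -1.34, percentile 0.01), including the matrix gene Thbs1 at 37.5 against 152. Outside the lists Procr (222 against 18.1), Gpnmb (276 against 30.7) and Serpine2 (149 against 21.2) had the highest ratios. Nnmt (42.8 against 161), Scd2 (45.3 against 156) and Lamb1 (44.1 against 146) had the lowest.

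Between the neonatal and 2 month libraries 85 of the 299 measured list members had at least 2-fold higher and 76 at least 2-fold lower CPM. The balance turned to 80 and 89 without mitochondrial, ribosomal-protein and haemoglobin genes, was 98 and 64 with TMM scaling, and over all 8791 measured genes was 952 and 1474. Il1r2 differed by a log2 ratio of 6.57 (6.42 to 6.73), C3 by 8.10 (7.87 to 8.34), Cxcl13 by 7.27 (6.83 to 7.75) and Mmp3 by 6.85 (6.68 to 7.02). Fabp4 differed by -7.82 (-8.10 to -7.56), Dlk1 by -9.58 (-9.83 to -9.34) and H19 by -10.96 (-11.60 to -10.38). Dkk1, at 23.5 CPM in the neonatal library, had no UMI at 2 months, so it was at least 419.8-fold lower against a floor of 3 counts in that library. List medians were 1.68 for IL-1 (6 higher and 0 lower of 11), 2.37 for interferon (13 and 0 of 17), 3.54 for chemokine and complement (9 and 0 of 11) and 1.38 for matrix turnover (9 and 1 of 16). They were 0.72 for adipose progenitor (5 and 2 of 12), 0.29 for TGF-beta and BMP (6 and 3 of 23) and 0.14 for NF-kB response genes (7 and 2 of 26). The percentiles of these lists ran from 97.7 to 100. Medians were -3.11 for cell cycle (0 and 23 of 24), -0.94 for WNT target (0 and 5 of 14) and -0.74 for imprinted and growth genes (4 and 8 of 19), with percentiles of 0, 0.15 and 1.14. The inflammatory myeloid list (1 and 3 of 4) had a median of -2.24 and percentile 0.03, the antimicrobial list (1 and 0 of 2) 4.43 and 99.6, and the resident macrophage list (2 and 0 of 3) 2.89 and 98.2. A further 5 lists lay between percentiles 35.6 and 62.2, the adipocyte (3 and 6 of 20, median -0.34), collagen (5 and 8 of 30, -0.40), WNT ligand and receptor (2 and 5 of 22, -0.40), WNT antagonist (3 and 5 of 14, -0.18) and hair follicle mesenchyme lists (3 and 4 of 10, -0.26).

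**Figure D4:**
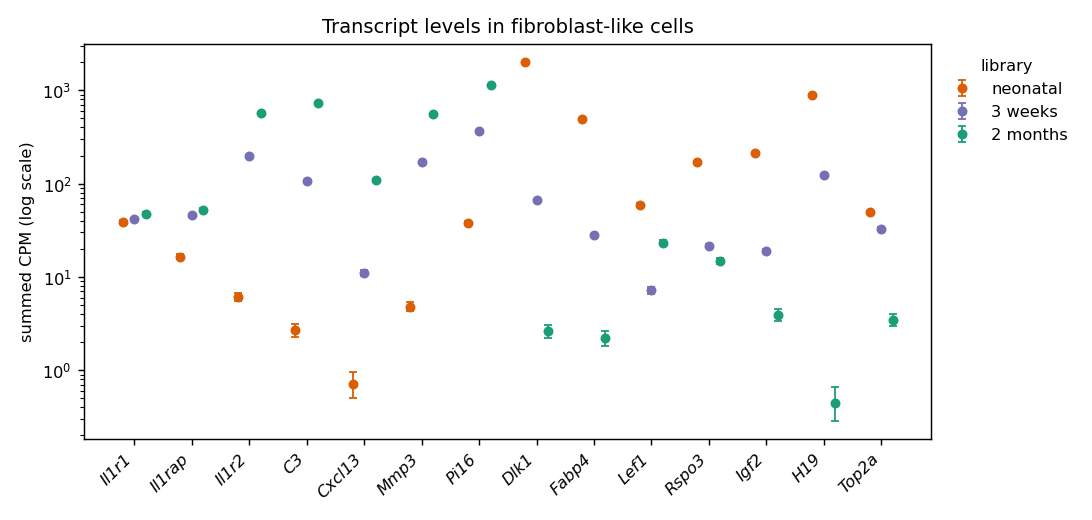
Summed CPM (log scale, vertical axis) of 14 named genes (horizontal axis) in the fibroblast-like cells of the 3 libraries, 1 library per age; whiskers are exact 95% Poisson intervals, hidden by the points where narrow. Il1r2 stood at 6.07, 199 and 578 CPM, Fabp4 at 498, 27.9 and 2.20 CPM and Lef1 at 59.7, 7.18 and 23.3 CPM.

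Several other properties differed between the libraries. Ribosomal-protein genes took 23.0% of the fibroblast-like UMIs in the neonatal library, 10.8% at 3 weeks and 10.6% at 2 months, and the 10 most abundant genes took 10.9%, 24.5% and 25.8%. The median log2 ratio of all measured genes was -0.19 at 3 weeks over neonatal, -0.08 at 2 months over 3 weeks and -0.28 at 2 months over neonatal. It became 0.05, -0.02 and 0.01 with TMM scaling and -0.43, -0.10 and -0.54 without mitochondrial, ribosomal-protein and haemoglobin genes. Between those scalings the median changed sign at 3 weeks over neonatal for the NF-kB, TGF-beta and BMP, WNT ligand and receptor, collagen, imprinted and dissociation lists. It changed sign at 2 months over 3 weeks for the adipocyte, adipose progenitor and antimicrobial lists, and at 2 months over neonatal for the NF-kB, dissociation, WNT antagonist and hair follicle lists. Collagen and matrix genes had a summed CPM of 67895, 217720 and 212380, so all other genes shared a smaller remainder in the older libraries. The summed CPM of the dissociation and heat shock list was 33554, 34457 and 41841. Its medians were -0.07 (percentile 58.6, 2 higher and 3 lower of 24) at 3 weeks over neonatal, 0.28 (percentile 99.9, 0 and 0) at 2 months over 3 weeks and 0.17 (percentile 95.04, 6 and 3) at 2 months over neonatal. Xist stood at 628, 0.102 and 0.0933 CPM and the Y-linked gene Ddx3y at 36.0, 97.8 and 112, so the neonatal library held cells of both sexes and the others nearly none with Xist. The sex-linked list had medians of 0.36, 0.13 and 0.53 for the 3 pairs, inside the random range, with 1 higher and 1 lower of 4 members in both comparisons with the neonatal library and none between the older libraries. Markers of contractile cells, Acta2 and Tagln, stood at 239 and 217 CPM in the neonatal fibroblast-like sum, 29.6 and 28.2 at 3 weeks and 4.85 and 6.62 at 2 months.

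The cell cycle and WNT target lists depended on which fibroblast-like cells were compared, in subsets chosen after the data were seen. Within reticular-like cells the cell cycle median at 2 months over 3 weeks was 0.28 (percentile 67.8, 14 members) and at 2 months over neonatal -0.58 (percentile 6.32). Within interstitial progenitor-like cells these were -0.98 (percentile 0.12, 9 members) and 0.00 (percentile 44.8). Subclusters led by cell cycle genes, with 415 neonatal and 255 3 week cells, stayed unnamed and so lay outside both subsets. The WNT target median at 3 weeks over neonatal was -0.50 (percentile 0.42) in interstitial progenitor-like and -0.35 (percentile 2.33) in reticular-like cells. At 2 months over neonatal it was -0.42 (percentile 2.72) and 0.08 (percentile 52.7). The IL-1, interferon and chemokine and complement lists stayed above percentile 99 for all 3 pairs of ages in both subsets. Makeup was not held equal within the reticular-like subset. Of its 446 cells at 2 months, 142 lay in a subcluster with Spp1, Vwa1 and Apod among its leading genes. A 3 week subcluster of 83 cells that Vwa1 and Apod also led stayed unnamed. Of its 490 neonatal cells, 214 lay in a subcluster with 4 preadipocyte markers.

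The preadipocyte-like cells were compared with the other fibroblast-like cells of the neonatal and 3 week libraries, the 2 libraries that held both, to ask how the IL-1, NF-kB and WNT genes stood in cells of the adipogenic state. Preadipocyte-like cells carried more transcript of NF-kB response genes and of Il1r1, and less of WNT target, WNT antagonist and cell cycle genes, than all other fibroblast-like cells. None of these lists passed with an estimated correlation (camera adjusted p = 0.47). That form had 1 residual degree of freedom and little power, so it does not decide whether the lists differ. The NF-kB, WNT target and cell cycle results did not hold against a narrower set of other cells. Il1r1 was higher, at 90.4 against 31.3 CPM in the neonatal library and 116 against 39.2 at 3 weeks. Its log2 ratio was 1.54 ± 0.15 (SE from the F statistic, n = 2 libraries, edgeR adjusted p = 0.024). Il1r1 was the only member of the IL-1 list of 15 to pass (3 higher, adjusted over the list alone, median 0.13). Il1rap gave -0.13 ± 0.22 (adjusted p = 0.82). NF-kB response genes had 8 of 30 members higher and 0 lower (21 and 0, adjusted over the list alone), and a median log2 ratio of 1.03. That count depended on the setting, from 1 higher when clustered with the list genes and 2 at resolution 0.5 to 19 with DESeq2 and 20 of 33 with no filter, and was 0 without the library block. Tnfaip2 rose by 2.19 ± 0.20, Cxcl1 by 1.78 ± 0.21, the chemokine gene Ccl7 by 1.75 ± 0.18 and Ptgs2 by 1.55 ± 0.16. WNT target genes had 1 of 17 higher and 7 lower (1 and 11, adjusted over the list alone), with a median of -2.25. When clustered with the list genes 2 were lower. Tnfrsf19 gave -4.11 ± 0.36, Nkd2 -3.66 ± 0.25, Lef1 -3.37 ± 0.34 and Nkd1 -2.25 ± 0.24, and the gene that was higher was Myc, a growth regulator, at 1.15 ± 0.15. Beside these, dissociation and heat shock genes had 5 of 25 members higher and 0 lower (7 and 0, adjusted over the list alone), with a median of 0.40, led by Atf3, Dnajb1, Junb and Egr1.

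Against a narrower set of other cells neither list result held. With interstitial progenitor-like and reticular-like cells as the other cells, an alternative chosen after the data were seen, the NF-kB median was 0.07 (camera adjusted p = 0.55) and the WNT target median 0.36 (adjusted p = 0.81). The cell cycle median was -0.18 (adjusted p = 0.39). Of the 490 neonatal reticular-like cells, 214 lay in a subcluster that itself held 4 preadipocyte markers, which could have lessened the NF-kB and WNT target ratios. At 3 weeks no reticular-like subcluster held more than 2. By library the medians against this narrower set were 0.28 (neonatal) and -0.14 (3 weeks) for NF-kB response genes. For WNT targets they were 0.49 and 0.27. Against all other fibroblast-like cells camera with a preset correlation gave adjusted p = 9.95e-18 for the NF-kB response list, 5.56e-15 for WNT targets, 1.99e-33 for cell cycle, 5.84e-07 for WNT antagonists and 6.73e-05 for dissociation genes. No list passed with an estimated correlation (adjusted p = 0.47 for each of these except 0.49 for dissociation genes). Its 1 residual degree of freedom left little power. For WNT targets the estimated correlation was -0.059, yet the unadjusted camera p went from 8.34e-16 to 0.073. Against all other fibroblast-like cells the per-library medians were 1.16 and 0.80 for NF-kB response genes and -1.92 and -1.92 for WNT targets in the neonatal and 3 week libraries.

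**Figure D5:**
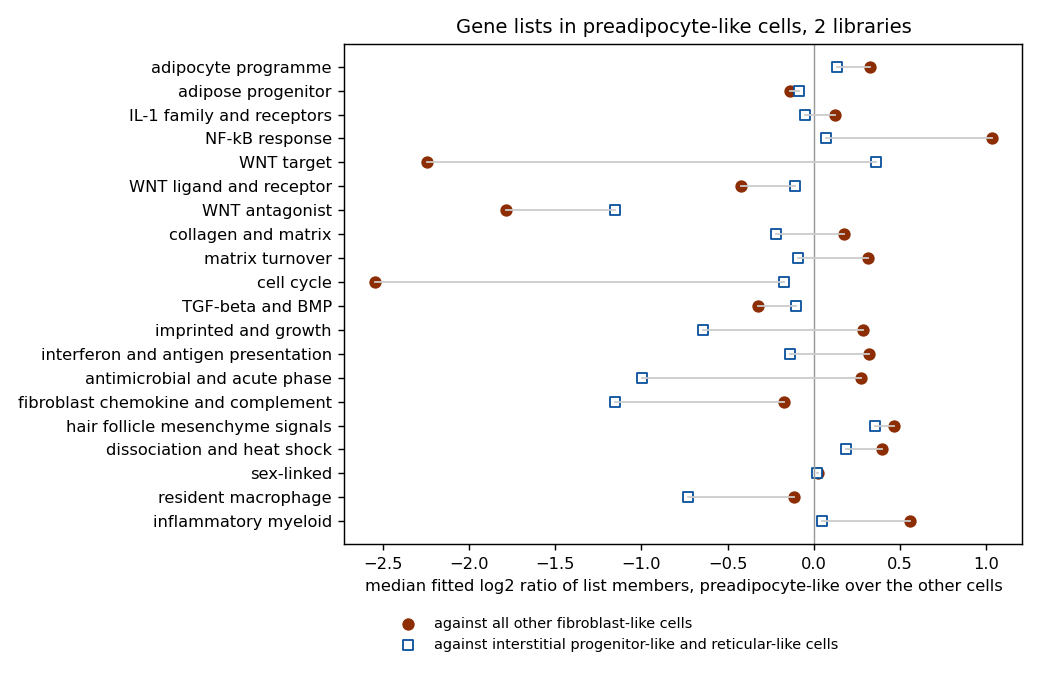
Median fitted log2 ratio of the tested members of each gene list (horizontal axis) in preadipocyte-like cells over all other fibroblast-like cells (filled circles) and over interstitial progenitor-like and reticular-like cells alone (open squares), from 2 libraries; lines join the values of a list. The NF-kB response list stood at 1.03 and 0.07 and the WNT target list at -2.25 and 0.36.

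Among WNT ligands and receptors 2 of 30 were higher and 3 lower (3 and 7, adjusted over the list alone, median -0.42). Rspo1 stood at -4.07 ± 0.20, Rspo3 at -4.32 ± 0.36, and the receptor genes Fzd4 at 2.29 ± 0.18 and Lgr4 at 1.62 ± 0.20. WNT antagonists had 0 of 16 higher and 4 lower (0 and 9, adjusted over the list alone, median -1.79), namely Sfrp2 at -2.20 ± 0.26, Dkk1, Frzb and Sostdc1. Cell cycle genes had 0 of 24 higher and 12 lower (0 and 19, adjusted over the list alone, median -2.55), among them Birc5 at -3.08 ± 0.25 and Stmn1 at -2.55 ± 0.19. The other cells included unnamed subclusters led by cell cycle genes, with 415 neonatal and 255 3 week cells. Any state without such cells would stand lower, so this result is not particular to preadipocyte-like cells. Of the 18 tested members of the adipocyte list outside the markers that named the state, Cfd was the 1 that passed, at 3.00 ± 0.35 (4 higher and 0 lower, adjusted over the list alone, median 0.32). These members could enter the variable genes that formed the subclusters, so they are not independent of the state. In the adipose progenitor list 3 of 12 were higher and 2 lower (4 and 2, adjusted over the list alone, median -0.13). Ly6c1 stood at 1.51 ± 0.15, Ly6a at 1.47 ± 0.19, Cd24a at -2.42 ± 0.19 and Pi16 at -3.21 ± 0.37. Chemokine and complement genes had 3 of 13 higher and 0 lower (5 and 1, adjusted over the list alone), with Cxcl12 at 2.28 ± 0.19. Their median was -0.17 although camera gave the direction up (adjusted p = 0.020, and 0.47 with the estimated correlation). By library it was 0.86 in the neonatal library and -0.12 at 3 weeks, so the libraries differed in sign. Against interstitial progenitor-like and reticular-like cells the direction was down (adjusted p = 1.87e-06, and 0.77 with the estimated correlation). TGF-beta and BMP genes had 0 of 23 higher and 2 lower, Ctgf at -2.54 ± 0.22 and the BMP antagonist gene Grem1 at -4.13 ± 0.50 (6 and 10, adjusted over the list alone, median -0.32). Matrix turnover genes had 2 of 16 higher, Plat at 1.63 ± 0.15 and Adamts1 at 1.09 ± 0.15 (5 and 0, adjusted over the list alone, median 0.32). The collagen list had 1 of 30 higher, Postn at 1.94 ± 0.28 (3 and 1, adjusted over the list alone, median 0.17). The imprinted list had 1 of 19 higher, Cdkn1c at 1.36 ± 0.16 (4 and 1, adjusted over the list alone, median 0.29). Hair follicle mesenchyme genes had 1 of 11 lower, Crabp1 at -3.18 ± 0.24 (4 and 4, adjusted over the list alone), with a median of 0.47 and the camera direction down (adjusted p = 0.64). Inflammatory myeloid genes had 2 of 8 higher, Thbs1 and Cxcl2, and 1 lower, Plac8 (median 0.56). No member passed in the interferon (19 tested, median 0.32), antimicrobial (10, 0.27), sex-linked (5, 0.03) and resident macrophage lists (6, -0.11). Adjusted over the list alone 1, 1, 0 and 1 were higher.

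Over all 13619 genes tested, 132 were higher and 191 lower at a false discovery rate of 0.05, of which 126 and 191 were outside the state markers. Genes of the adipocyte list and outside the lists could also be among the variable genes that formed the subclusters. The rate of 0.05 is therefore nominal, since the states were taken from the same cells. The fit had 1 residual degree of freedom, and without the library block no gene passed in edgeR (277 higher and 511 lower at an unadjusted p under 0.05). Preadipocyte-like cells held more UMIs per cell than the class, with medians of 13063 against 8454 in the neonatal library and 15312 against 12106 at 3 weeks.

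Among classes of 50 or more cells Il1b and Il1a were highest in macrophage-like cells and Il1r1 in mural-like cells, while Il1rap was spread over several classes. Il1b, which encodes the secreted cytokine, stood at 7036 CPM in neonatal macrophage-like cells (6893 to 7181, 61.8% of 110 cells with a UMI). It stood at 1317 at 3 weeks (1247 to 1390.4, 16.2% of 179 cells) and 386 at 2 months (350.2 to 425, 25.1% of 263 cells). In dendritic or Langerhans-like cells it stood at 775 CPM at 3 weeks and 377 at 2 months, and in fibroblast-like cells at 1.13, 0.524 and 0.0933. Il1a stood at 429, 7.02 and 18.3 CPM in macrophage-like cells, and the receptor antagonist gene Il1rn at 58.2, 70.4 and 56.5 in keratinocyte-like cells. Il1r1 in mural-like cells stood at 146, 80.2 and 106 CPM, followed by fibroblast-like cells at 38.9, 41.7 and 47.4. Il1rap stood at 115, 46.7 and 28.3 CPM in Schwann-like cells, most of them in cluster 26 in the neonatal and in cluster 18 in the older libraries, and 16.5, 46.0 and 52.8 in fibroblast-like cells. Median depth of the macrophage-like cells was 11553.5, 5091 and 3432 UMIs.

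WNT ligand transcripts lay in several classes, keratinocyte-like and fibroblast-like cells among them. Basal cluster 12, which Wnt10a helped to mark, held 9 of 193, 487 of 1395 and 336 of 1690 keratinocyte-like cells, so values of that class compare different clusters. Keratinocyte-like cells held Wnt4 at 260.2, 274 and 148.5 CPM, Wnt10a at 13.2, 129 and 79.1, Wnt3 at 29.2, 81.2 and 58.7, and Wnt7b at 94.6, 55.3 and 37.3, where fibroblast-like cells stayed below 1 CPM for Wnt3 and Wnt7b. Fibroblast-like cells held Wnt5a at 31.2, 73.4 and 64.1 CPM, Wnt11 at 39.6, 38.5 and 46.1, and Wnt2 at 15.5, 14.9 and 26.7, and Schwann-like cells held Wnt6 at 81.9, 83.6 and 50.3. Wnt11 was also present in T or innate lymphoid-like cells, at 75.2 CPM at 3 weeks and 32.6 at 2 months. Wnt16 reached 16.4 CPM in neonatal keratinocyte-like cells and Wnt5b 12.9 in fibroblast-like cells at 3 weeks. Wnt9a reached 21.1 in dendritic or Langerhans-like cells at 2 months and Wnt10b 17.5 in T or innate lymphoid-like cells at 2 months. Wnt2b, Wnt3a and Wnt7a stayed below 7 CPM in each class.

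The genes named most often lie at single positions of the mm10 build by the GENCODE annotation. Il1r2 (ENSMUSG00000026073) and Il1r1 (ENSMUSG00000026072) are neighbours on chromosome 1, at 40074079 to 40125231 and 40225080 to 40317257, and Il1rap (ENSMUSG00000022514) lies on chromosome 16 at 26581704 to 26730117. Il1b (ENSMUSG00000027398) lies on chromosome 2 at 129364570 to 129371139, Fabp4 (ENSMUSG00000062515) on chromosome 3 at 10204088 to 10208576, Lef1 (ENSMUSG00000027985) on chromosome 3 at 131110471 to 131224356 and Dlk1 (ENSMUSG00000040856) on chromosome 12 at 109452823 to 109463336. All are protein-coding genes.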

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

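The tests of the makeup of the other cells, of dermal papilla-like and dermal sheath-like cells, of the sex of the animals and of the dissociation response in macrophage-like cells were chosen after their results were seen. Those of the dissociation response in NF-kB genes, of depth at 2 months and of neutrophils were chosen before.

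In 4 cases a list stood in opposite directions in 2 cell classes for the same pair of ages, a difference that was not tested. The cell cycle list at 3 weeks over neonatal had a median log2 ratio of 1.12 in keratinocyte-like and -0.53 in fibroblast-like cells. The IL-1 list at 2 months over neonatal had -0.74 in macrophage-like and 1.68 in fibroblast-like cells. The interferon list at 3 weeks over neonatal had -0.86 in mural-like and 1.73 in fibroblast-like cells, and the matrix turnover list at 2 months over neonatal -0.75 in mural-like and 1.38 in fibroblast-like cells. Different clusters held much of the keratinocyte-like class in these libraries and part of the mural-like class at 3 weeks. Suprabasal cluster 15 held 132 of 193 neonatal and 302 of 1395 keratinocyte-like cells at 3 weeks, and mural-like cluster 34 held 0, 122 and 16 cells from neonatal to 2 months. Of the macrophage-like cells 35 of 110 had a neutrophil marker UMI in the neonatal library and 22 of 263 at 2 months. Such makeup was not separated from age in those values.

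Some signals lay in cells that no comparison used. Cluster 9, led by Gzmc, Icos, Ccl5 and Cd69, lymphocyte genes, held 271 cells at 3 weeks and 661 at 2 months. Cluster 23, led by Lhx2, Dct, Pmel and Ptgds, hair follicle and pigment genes, held 124, 95 and 85 cells in the neonatal, 3 week and 2 month libraries. Cluster 25, led by the muscle genes Myog, Actc1, Cdh15 and Jsrp1, held 103, 92 and 59 cells. Cluster 35, led by the Langerhans cell gene Cd207 and class II genes, held 34 cells at 3 weeks and 58 at 2 months. It also carried basal keratinocyte markers and a median of 3.00 times the median UMIs of the library, as doublets would. Sex was not compared. Of the neonatal cells 59.5% had an Xist UMI and no Y-linked UMI, and these cells were kept in the comparisons by age. With only neonatal cells that had a Y-linked UMI and no Xist UMI, an alternative added after the data were seen, 75 list genes were at least 2-fold higher and 54 lower at 3 weeks over neonatal.

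In preadipocyte-like cells NF-kB response genes stood higher (median log2 ratio 1.03) and WNT target genes lower (-2.25) than in all other fibroblast-like cells. The dissociation response as the whole cause is argued against. With cells split by dissociation share into 3 bins the mean of the NF-kB medians was 1.21 in the neonatal library, no lower than the unmatched 1.16, and 0.88 against 0.80 at 3 weeks. From the lowest to the highest share the medians were 1.72, 1.13 and 0.78 in the neonatal library and 1.08, 0.92 and 0.65 at 3 weeks. The ratio was thus smaller among cells with a high share, and a part of it from dissociation stays open. Dermal papilla-like and dermal sheath-like cells among the others do not account for it either, since without them the medians were -2.26 for WNT targets and 0.90 for NF-kB response genes. The makeup of the other cells as a whole remains a candidate explanation for both lists, because against interstitial progenitor-like and reticular-like cells the medians were 0.36 for WNT targets and 0.072 for NF-kB response genes. Part of that set, 214 neonatal reticular-like cells, held 4 preadipocyte markers itself, so the set was not free of adipogenic markers. At 3 weeks no reticular-like subcluster held more than 2, and the medians there were -0.14 for NF-kB response genes and 0.27 for WNT targets. The neonatal subcluster therefore does not account for the 3 week values. Whether the adipogenic state itself takes part was not settled by these tests.

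No subcluster at 2 months was named preadipocyte-like. Lower depth is argued against, as at 1500 UMIs per cell the share of fibroblast-like cells with 3 or more preadipocyte markers was 0.149% at 2 months (interval 0.0599 to 0.307%) and 0.834% at 3 weeks (0.611 to 1.11%). The sex of the animals alone is argued against, as the 3 week library, which also nearly lacked Xist, held 240 preadipocyte-like cells. Age remains an open biological explanation that 1 library per age could not test, and so does a difference in which cells dissociation released, which these files do not measure.

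Il1b in macrophage-like cells was highest in the neonatal library, at 7036 CPM against 1317 and 386. Neutrophils as the main source are argued against, since the 75 neonatal cells without a neutrophil marker UMI held 5787 CPM (interval 5640 to 5937), although the 35 cells with one held 11217 CPM. The median log2 ratio of the dissociation and heat shock list at 3 weeks over neonatal was 0.64 in these cells, higher at 3 weeks and not in the neonatal library. This argues against a response of the genes of that list only. The NF-kB response list stood lower at 3 weeks in these cells, so a response to dissociation outside the tested list stays open. Age stays open as an untested explanation, with 110 cells from 1 library behind the neonatal value.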

How the results depend on the processing

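The alternatives that narrowed the fibroblast-like cells or the other cells, or took neonatal cells by sex-linked UMIs, were chosen after the data were seen. Of 600 list medians by age under the alternatives chosen in advance 571 kept their side of the random range and 29 moved across it, and of 180 under those added later 138 kept it, 41 moved and 1 reversed. The order of the fibroblast-like shares held in each setting. With a 5% mitochondrial limit they were 87.7%, 68.2% and 56.7% from neonatal to 2 months, the 2 month share was 52.3% with doublets kept, and the 3 week share was 64.9% with each library clustered on its own. List genes with higher and lower CPM at 2 months over 3 weeks numbered 41 and 62 with no minimum, 51 and 34 in interstitial progenitor-like cells only and 51 and 39 in reticular-like cells only, and at 3 weeks over neonatal 51 and 36 in interstitial progenitor-like cells only. The antimicrobial list turned to a median of -1.42 at percentile 0.65 at 3 weeks over neonatal in reticular-like cells only. Cells with 3 or more preadipocyte markers were 15.04%, 12.5% and 5.74% with no thinning, and 2.43% (neonatal) and 0.525% (3 weeks) at 1000 UMIs. Of the preadipocyte-like shares of the class, those at resolution 0.5 were 15.6% (neonatal) and 13.7% (3 weeks), the neonatal share was 6.21% at resolution 2, those when clustered with the list genes were 9.37% and 3.72%, and the 3 week share was 5.66% with doublets kept. Genes higher and lower in preadipocyte-like cells numbered 398 and 418 with DESeq2, 219 and 292 with its size factors in edgeR, 456 and 700 with no filter (18347 tested), 0 and 0 with no library block in edgeR (277 and 511 unadjusted), and 307 and 451 at resolution 2. They numbered 247 and 349 with doublets kept, 65 and 127 against interstitial progenitor-like and reticular-like cells (11353 tested), 64 higher when clustered with the list genes and 705 lower at resolution 0.5. NF-kB response genes higher numbered 19 with DESeq2, 20 with no filter, 17 at resolution 2, 2 at resolution 0.5, 1 when clustered with the list genes, and 0 with no library block or against interstitial progenitor-like and reticular-like cells, where 1 was lower. WNT targets lower numbered 2 when clustered with the list genes and 0 with no library block or against that narrower set, and WNT targets higher 0 in those last settings and at resolution 0.5. Over all lists 123 of 320 such counts moved by more than 1.5 times under alternatives chosen in advance, and 32 of 80 under those added later. Against interstitial progenitor-like and reticular-like cells camera's adjusted p was 0.55 for NF-kB response genes. Among lists that had passed against all other fibroblast-like cells, the direction there turned for WNT targets (0.81), chemokine and complement (1.87e-06), imprinted (5.29e-05), interferon (0.081) and matrix turnover genes (0.74). With the estimated correlation in that setting chemokine and complement and imprinted genes both gave 0.77. In the other settings with the preset correlation it ranged from 1.68e-18 to 1.33e-10 for NF-kB response genes and from 3.03e-15 to 5.38e-06 for WNT targets, and with the estimated correlation from 0.25 to 0.72 for both. In the comparison against all other fibroblast-like cells both gave 0.47 with it, where 1 residual degree of freedom left little power. Except for the number of genes tested, the cause was not tested. Leaving out either library left 1 library and no residual degree of freedom, so only the per-library medians remain, 0.80 to 1.16 for NF-kB response genes and -1.92 to -1.92 for WNT targets. Depth limits the shares of cells with a UMI, of which 93 of 114 moved outside the interval at another depth. Of 216 class shares 61 moved, such as 38 neonatal T or innate lymphoid-like cells at resolution 2 against 1, and mast-like cells at 3 weeks at 0.187% with a 5% mitochondrial limit against 0.808%.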

Other observations

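No test in this part was planned as a comparison, and its values describe 1 library per age. Macrophage-like cells of the older libraries carried transcripts of the Cd209 lectin family that were rare in the neonatal library. At 3 weeks Cd209d stood at 340.1 against 3.81 CPM, Cd209a at 175 against 0.762 and Cd209f at 168.5 against 4.57, with a UMI in 20.7%, 17.9% and 13.4% of the 3 week cells. At 2 months Cd209g stood at 248 against 53.2 at 3 weeks. A minority of the neonatal cells held the neutrophil and stefin genes Stfa1 (1162 CPM, 21.8% of cells with a UMI) and Retnlg (583.5 CPM, 11.8%), both without a UMI at 3 weeks. The NF-kB response list had 1 of 30 members with higher and 15 with lower CPM at 3 weeks over neonatal in these cells (median log2 ratio -0.92, percentile 0). The resident macrophage list had 8 of 11 higher and 0 lower (median 1.39, percentile 100). In keratinocyte-like cells the stefin family genes Stfa3 and BC100530 stood at 11.3 against 6680 and 10.02 against 10447 CPM at 3 weeks over neonatal, and the epidermal keratin gene Krt77 at 3470 against 85.7. Suprabasal cluster 15 held 132 of the 193 neonatal cells and 302 of the 1395 at 3 weeks, so the list medians of the class compare different mixtures of clusters. The interferon list had 9 of 13 higher and 0 lower members there (median 2.98, percentile 100), and the cell cycle list 14 of 24 higher and 0 lower (median 1.12, percentile 100).

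Of the Schwann-like cells cluster 18 held 4, 178 and 383 and cluster 26 held 122, 77 and 43 from neonatal to 2 months, so different clusters are compared. Schwann-like cells at 2 months, against the neonatal library, held more of the myelin-associated dystrophin family gene Drp2 (739 against 3.03 CPM) and of Spp1 (1044 against 6.06). They held less of the growth cone gene Gap43 (1.38 against 192) and of Gfra3 (4.83 against 345). Their collagen and matrix list had 2 of 30 members with higher and 23 with lower CPM (median -1.74, percentile 0). Mural-like cells joined cluster 17 (192, 188 and 213 cells) with cluster 34, led by Cnn1, Actg2 and Des (0, 122 and 16), so the values at 3 weeks mix clusters. In mural-like cells the adrenergic receptor gene Adra2a stood at 1.31 against 157 CPM and the potassium channel gene Kcnj8 at 9.59 against 299.6 at 3 weeks over neonatal. At 2 months over 3 weeks Pln, a regulator of the calcium pump, stood at 352 against 57.6. Their NF-kB response list had 0 of 26 higher and 17 lower members at 2 months over neonatal (median -1.48, percentile 0). In T or innate lymphoid-like cells at 2 months over 3 weeks the interferon list had 3 of 15 higher and 0 lower members (median 0.54, percentile 99.95), and Apobec3 stood at 135 against 21.8 CPM. The dissociation and heat shock list stood higher at 2 months over neonatal in keratinocyte-like (median 1.14), Schwann-like (1.07) and macrophage-like cells (1.26). A small cluster led by the mature adipocyte genes Car3, Cfd and Adipoq held 34 neonatal cells, 6 at 3 weeks and 5 at 2 months, and was left unnamed. Its cells held a median of 3.07 times the median UMIs of their library.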
